A study of Arabidopsis thaliana with 24 samples.

How the data were processed

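Gene expression was measured with 1-colour Agilent arrays in 24 samples of 17-day-old Arabidopsis thaliana seedlings, 1 array per sample and 3 per group. The 8 groups combine genotype (Col-0 wild type or ap1-15), spray (mock or 100 µM GA3) and time after spraying (30 or 60 min), and the groups were read from the labels. Per the labels, seedlings grew at 22 °C in continuous light of 120 µE and received 10 µM paclobutrazol for 2 days before spraying, and 150 ng of total RNA per sample was labelled with Cy3.

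Per the file headers, the intensities of the deposited scanner files are processed signals that Agilent Feature Extraction 11.0.1.1 (protocol GE1_1010_Sep10) had subtracted for background and detrended within each array, with no normalization between arrays. The deposited intensity table of the series holds the same numbers, with a largest relative difference of 0, so its linear scale, its lack of centring and its direction are known. Its column medians over all spots were, for replicates 1, 2 and 3, 810, 864 and 740 in wild-type mock at 30 min, 705, 674 and 646 in wild-type GA3 at 30 min, 732, 696 and 740 in wild-type mock at 60 min, and 623, 788 and 792 in wild-type GA3 at 60 min. In ap1-15 they were 701, 914 and 790 in mock at 30 min, 742, 875 and 832 in GA3 at 30 min, 669, 733 and 758 in mock at 60 min, and 673, 637 and 680 in GA3 at 60 min.

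Each array held 45220 spots, of which 43803 were not controls, for 43603 distinct probes. The chip gives a locus for 38413 probes, of which 37943 matched the reference gene table and 470 did not, and 5190 probes had no locus. The table was used for names and for matching probes to current loci, and the neighbours of AP1 were taken in the order of their locus numbers. Because the header names an older genome build, no positions are given. On 0 spots was the signal saturated, and the 2 to 25 outlier spots of an array were set to missing, 65 values among the probes tested.

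Signals were taken to log2 and set relative to the 75th percentile of their array, which ran from 3401 to 5007 intensity units. A probe was kept if it was well above background, by the scanner's own call, on all 3 arrays of at least 1 group, which left 34121 probes. A gene was represented by its brightest probe, and 6540 of the genes had several, giving 25657 genes and transcripts, 22589 of them with a locus. Where a group was not well above background on any of its 3 arrays, the fold is given as a lower bound. It is the brighter group's mean over the dimmer group's mean with each dim array raised at least to its own lowest signal called well above background, and no fold is given where both groups were dim.

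A model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with 16 residual and 2.02 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each of 14 comparisons. These were GA3 against mock for each genotype and time and averaged over genotypes, the interactions of genotype and GA3 and of time and GA3, ap1-15 against wild type in mock and over the 4 conditions, and mock at 60 against 30 min. All tests were 2-sided. Exact permutation tests of AP1 and of the size of the response exchanged arrays within conditions.

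The comparisons, the filter, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Named genes were the 10 with the largest rise and the 10 with the largest fall past the threshold whose arrays of one group all lay above those of the other, up to 10 per direction for interactions, AP1, and members of the lists. The 16 genes lower in all 4 GA3 comparisons were singled out after their values were seen. The 20 lists held 279 entries for 273 loci, 6 of them on 2 lists, and 255 loci were tested. The DELLA early targets share SCL3, GID1A and GID1B with the list of GA perception and GA20OX2 and GA3OX1 with that of GA synthesis. Results of these lists are therefore not independent. Floral LFY and the meristem genes WUS and CLV3 did not pass the filter. CAO and SAUR21 were kept at the loci first written down, although the reference table puts these symbols elsewhere and the rule let the symbol decide, and with the table's loci 61 list tests were called rather than 62. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the 20 lists of a comparison. Over all comparisons 62 list tests were called with the preset, 13 of these with the estimated correlation and 36 by fry.

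Slides were read from the file headers. Slide was entered as a random block, with a consensus correlation of 0.20, and, after the layout had been seen, as a fixed term that sets GA3 arrays against the mock array of their slide (12 residual degrees of freedom). All arrays carry 1 scan date. The method was tested on simulated data with the means and spreads of the real genes, independent errors and 200 changed genes per comparison. Of 50 genes changed 2-fold, 45 were recovered for GA3 against mock in wild type at 30 min, 41 within slides, and 38 for the interaction at 30 min, 24 within slides. Other alternatives were quantile normalization, no filter, a stricter filter, the mean of the probes, an intensity trend, replicate number as a block, normexp background correction with an offset of 50, leaving out each array, leaving out 2 arrays that stood apart, and fitting the compared groups alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.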

Results

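Transcript levels were measured in 24 samples of Arabidopsis thaliana seedlings, 3 for each of 8 groups. Wild type (Col-0) and ap1-15, a mutant of the floral identity gene APETALA1 (AP1), were sprayed with a mock solution or with 100 µM gibberellin A3 (GA3) and collected after 30 or 60 min. Per the labels, the plants had spent 15 days on growth medium and 2 days on 10 µM paclobutrazol, which blocks gibberellin (GA) synthesis, and the 3 samples of a group were biological samples. Each sample was labelled with Cy3 and hybridised to its own 1-colour Agilent array of 45220 spots. Between 68.1% and 80% of the spots of an array lay well above background. The median signal ran from 679 to 1004 intensity units. The number of arrays, 3 per group, limits the precision. Changes are log2 values ± standard error from limma with n = 3 arrays per group. The size of a change is uncertain for a gene above background on 1 of the 3 arrays of a compared group. Examples below are AT5G44770, AT5G55150, AT3G03290, AT3G07250, HSP17.6A, AT1G12890, PKS4, IREG1 and 4CL8. A gene rose or fell where its p, adjusted over 25657 genes and transcripts, lay under the threshold of 0.05. The arrays lay on 8 slides. For each genotype and time mock replicates 1 and 2 shared a slide without GA3 arrays while mock replicate 3 lay with the 3 GA3 arrays. The standard deviation of log2 differences had a median of 0.272 for mock pairs on 1 slide and 0.373 for mock pairs on 2 slides. Results within slides, from the mean of the 3 GA3 arrays minus the mock array of their own slide, are therefore given beside the GA3 changes, as counts, as calls and for some genes as values. They were chosen after seeing the data.

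AP1 (AT1G69120), which encodes a MADS-box factor of floral meristem and sepal identity, was lower in ap1-15 than in wild type in all 4 conditions. On the log2 scale relative to the 75th percentile of the array, the 12 wild-type arrays lay between −4.70 and −3.56 and the 12 ap1-15 arrays between −8.10 and −6.17. The mean difference was −3.00 ± 0.15, with adjusted p = 4.14e-10 in limma and p = 1.25e-05 in a 2-sided exact permutation test within conditions, the smallest p its 160000 relabelings can give. In mock at 30 min the mean was −6.99 ± 0.74 (SD, n = 3) in ap1-15 and −4.20 ± 0.20 in wild type. The AP1 probe was well above background on 12 of 12 wild-type arrays and on 1 of 12 ap1-15 arrays, so the fitted fold is uncertain, and with another background correction chosen after seeing the data the mean difference was −1.47 (exact permutation p = 1.25e-05). Wild type was at least 2.19-fold higher with GA3 at 30 min, at least 4.22-fold higher in mock at 60 min and at least 8.48-fold higher with GA3 at 60 min. Within a single condition an exact permutation test of 3 arrays against 3 cannot go below p = 0.1, which each condition reached.

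**Figure D1:**
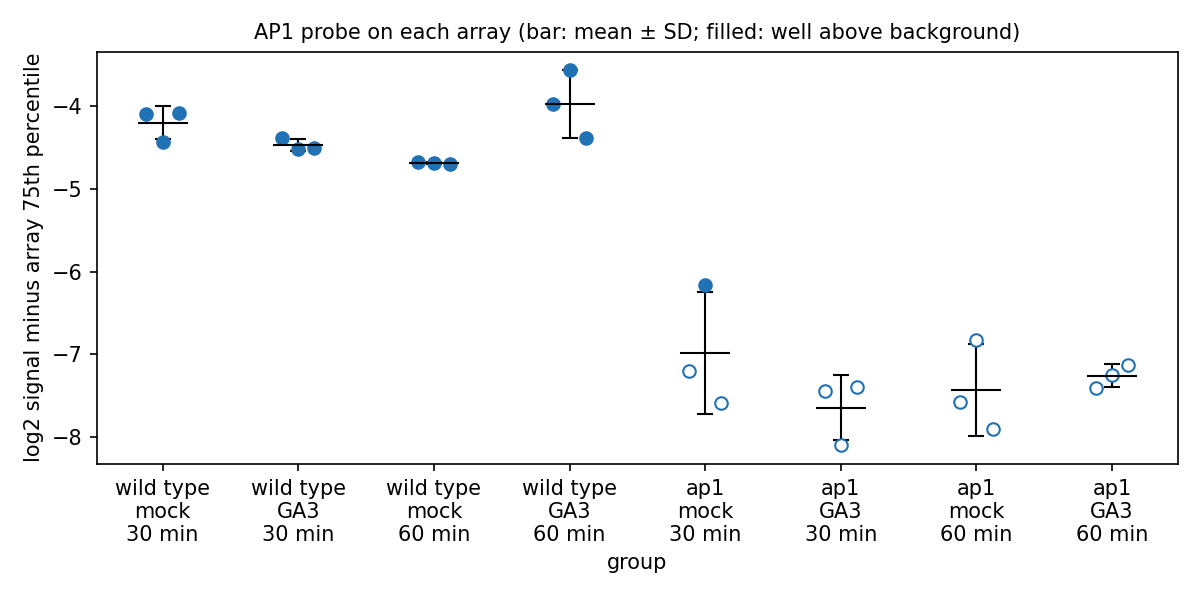
AP1 signal on each of the 24 arrays (vertical axis, log2 relative to the 75th percentile of the array), by genotype, treatment and time, with group means and standard deviations of 3 arrays; open points were not well above background. The wild-type arrays lie between −4.70 and −3.56 and the ap1-15 arrays between −8.10 and −6.17.

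GA3 against mock in wild type at 30 min shows the response at the earliest time sampled. Some genes of GA synthesis, perception and signalling fell. GA20OX3 (AT5G07200) and GA3OX1 (AT1G15550), which encode enzymes of the last steps of GA synthesis, changed by −1.51 ± 0.20 (adjusted p = 0.00219) and −1.03 ± 0.17 (adjusted p = 0.0118). The GA receptor gene GID1B (AT3G63010) changed by −0.94 ± 0.08 (adjusted p = 1.15e-05), and SCL3 (AT1G50420), a GRAS-domain regulator, by −0.81 ± 0.08 (adjusted p = 0.000111). Other genes that fell were the receptor gene GID1A (−0.52 ± 0.11), the RING-protein gene XERICO (−0.55 ± 0.07), the GATA factor gene GNL (−0.88 ± 0.17) and the MYB-like factor gene RVE1 (−0.99 ± 0.17). The NAC factor genes NAP and NAC047 changed by −1.13 ± 0.16 and −1.03 ± 0.14. SAUR69 (AT5G10990) changed by −1.14 ± 0.20, AT3G25013 by −1.30 ± 0.24, AT2G28690 by −0.97 ± 0.11 and AT2G20670 by −0.94 ± 0.18. The brassinosteroid synthesis gene DWF4 rose by 0.44 ± 0.06, KAO1, of the middle steps of GA synthesis, by 0.25 ± 0.06, and the bHLH gene PAR2 by 0.37 ± 0.09. Of 12 measured early targets of DELLA proteins, the growth repressors that GA removes, 6 fell and 0 rose (7 lower when adjusted over the list alone; camera adjusted p = 1.09e-06, and 0.000621 with an estimated correlation). Of 12 genes of GA perception and DELLA signalling, 3 fell and 0 rose (3 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.000551, and 0.035 with an estimated correlation). These 3, GID1A, GID1B and SCL3, are also among the DELLA early targets. GA synthesis had 2 of 10 members lower and 1 higher (4 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.153). Early auxin response genes were shifted up with 0 of 21 members called (0 when adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.713 with an estimated correlation). In all, 251 genes rose and 158 fell, but 0 were called by limma with only the compared groups in the fit. Without a filter 40 rose and 42 fell, and with slide as a random block 20 and 27, so the more frequent direction turned as well. That direction was kept with an intensity trend (446 and 263), the stricter filter (398 and 257) and a replicate block (137 and 96). The 10 genes named for their fitted rise were transcripts known from expressed sequence tags without a locus. Of these, 6 were not above background in mock and rose at least 1.01-fold to 2.13-fold, and the other 4 rose by 1.44 to 1.87 over all arrays but by 0.24 to 0.60 within slides. Within slides 1 gene rose and 13 fell, 5 of these 14 being called over all arrays too, among them GID1B (−1.02), SCL3 and AT2G28690 (−1.08), while GA20OX3 (−1.79, adjusted p = 0.0537), GA3OX1 (−1.36, adjusted p = 0.0643) and the other genes with a locus named above were not called. The count became 38, 23 and 5720 without mock replicate 1, 2 and 3, and 24, 151 and 29 without GA3 replicate 1, 2 and 3.

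At 60 min some GA synthesis, receptor and DELLA target genes fell in wild type. GA20OX3 was at least 4.49-fold lower with GA3, its GA3 arrays no longer being above background (adjusted p = 3.44e-08), and GA3OX1 changed by −2.43 ± 0.17 (adjusted p = 2.43e-07). GA20OX2 (AT5G51810) and GA20OX1 (AT4G25420), of the same enzyme family, changed by −2.20 ± 0.37 (adjusted p = 0.0118) and −1.57 ± 0.19 (adjusted p = 0.000423). GA20OX2 was above background on 1 of 3 GA3 arrays at 60 min in each genotype, so the size of its changes at that time is uncertain. SCL3 changed by −1.30 ± 0.08 (adjusted p = 5.18e-08), GID1B by −1.15 ± 0.08 (adjusted p = 1.45e-07) and XERICO by −0.78 ± 0.07 (adjusted p = 4.67e-06). GID1A (−0.61 ± 0.11), the calmodulin-binding protein gene IQD22 (−0.60 ± 0.10), AT3G11280 (−0.34 ± 0.06) and SLY1 (−0.45 ± 0.08), which encodes the F-box protein that targets DELLA proteins, also fell. So did AT1G12890 (−1.67 ± 0.21), AT2G34610 (−1.48 ± 0.16), AT4G08570 (−1.44 ± 0.15) and AT3G14260 (−1.11 ± 0.21). While 57 genes fell, 9 rose. These were the DELLA gene RGL1 (0.45 ± 0.08), the epidermal fate gene WEREWOLF (MYB66, 0.70 ± 0.11), TCP9 (0.66 ± 0.10), the zinc finger gene ZFP8 (0.52 ± 0.11) and the cytokinin oxidase gene CKX5 (0.43 ± 0.08). MYB84 (0.32 ± 0.05), AT3G43890 (0.63 ± 0.12), AT2G47440 (0.38 ± 0.08) and AT3G57800 (0.28 ± 0.05) were the others. Of the 12 DELLA early targets 8 fell and 0 rose (10 lower when adjusted over the list alone; camera adjusted p = 7.55e-34, and 1.21e-08 with an estimated correlation). Of 10 GA synthesis genes 4 fell and 0 rose (5 lower when adjusted over the list alone; camera adjusted p = 3.26e-12, and 0.000776 with an estimated correlation). GA perception and signalling had 4 members lower and 1 higher (4 and 4 when adjusted over the list alone; camera adjusted p = 0.0143, and adjusted p = 0.183 with an estimated correlation). Mitotic genes were shifted up and touch genes down with 0 of 15 and 0 of 17 members called (0 mitotic genes and 1 touch gene when adjusted over the list alone; camera adjusted p = 2.83e-07 and 0.00798, but 0.262 and 0.418 as adjusted p with an estimated correlation). Floral identity genes were shifted up and growth bHLH genes down with 0 of 14 and 0 of 17 called (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000888 and 0.0128, but 0.183 and 0.331 as adjusted p with an estimated correlation). Within slides limma called 5 genes lower and 0 higher (1572 at an unadjusted p under 0.05), namely GA20OX3, GA3OX1 (−2.29), SCL3 (−1.27), GID1B (−1.16) and XERICO (−0.78), whereas GA20OX2 (−2.04, adjusted p = 0.646) and GA20OX1 (−1.63, adjusted p = 0.1) were not called. With slide as a random block 5 rose and 37 fell. The count became 24 and 32 without mock replicate 1 and 2, and 34 and 27 without GA3 replicate 2 and 3.

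In ap1-15 the early response was measured against mock at 30 min in the same way. GA3OX1 changed by −1.33 ± 0.17 (adjusted p = 0.000332), GA20OX3 by −1.23 ± 0.20 (adjusted p = 0.00241), GA20OX1 by −1.20 ± 0.19 (adjusted p = 0.00219) and GA3OX2 by −0.91 ± 0.21 (adjusted p = 0.0188). SCL3 (−0.93 ± 0.08), GID1B (−0.89 ± 0.08), XERICO (−0.63 ± 0.07), the GA-repressed GATA factor gene GNC (−0.39), RVE1 (−1.06 ± 0.17), SAUR9 (−0.74 ± 0.17) and the boundary gene CUC3 (−0.58) fell as well. The DELLA gene GAI rose by 0.50 ± 0.10, the expansin gene EXPA5 by 0.59 ± 0.11, and the jasmonate repressor genes JAZ2 and JAZ5 by 0.62 ± 0.10 and 0.73 ± 0.21. KMD4 (AT3G59940), an F-box kelch gene, changed by −2.14 ± 0.16 (adjusted p = 3e-06). The floral organ gene AP3 rose from signals not above background on any mock array to 2 of 3 GA3 arrays above it, at least 4.1-fold. Other rises from a mock level under background were at least 11.6-fold for AT5G55150, 6.7-fold for AT3G24230, 4.97-fold for AT2G02110, 4.95-fold for AT2G24255, 3.84-fold for AT1G30180, 3.14-fold for bZIP75 and 2.17-fold for the expansin gene EXPB6. AT5G44770 rose by 2.98 ± 0.38. AT5G14360 was at least 1.55-fold lower with GA3, and 8 of the 10 largest falls were transcripts without a locus. Of the 12 DELLA early targets 6 fell and 0 rose (6 lower when adjusted over the list alone; camera adjusted p = 1.6e-05, and 0.00175 with an estimated correlation). Of 10 GA synthesis genes 4 fell (4 when adjusted over the list alone; camera adjusted p = 0.000923, and adjusted p = 0.122 with an estimated correlation). Jasmonate genes were shifted up with 2 of 17 called (5 when adjusted over the list alone; camera adjusted p = 0.00409, and adjusted p = 0.928 with an estimated correlation). Touch genes were shifted up with 0 of 17 called (0 when adjusted over the list alone; camera adjusted p = 0.0154, and adjusted p = 0.928 with an estimated correlation). On these arrays 68.1% to 72.5% of spots lay well above background with GA3 and 73.5% to 76.6% in mock. In all 567 genes rose and 1068 fell, or 255 and 593 with slide as a random block and 9 and 23 with only the compared groups in the fit. With another background correction chosen after seeing the data 609 genes rose and 538 fell, so the more frequent direction turned. Within slides 101 rose and 275 fell, 237 of them also called over all arrays, including GA3OX1, GA20OX1, SCL3, GID1B, XERICO, RVE1, EXPA5, JAZ2 and KMD4 but not GA20OX3 (adjusted p = 0.0653), AP3 (adjusted p = 0.183), GA3OX2, GNC, SAUR9, CUC3, GAI, JAZ5, AT5G55150, AT1G30180 or AT5G14360. The count became 452 and 584 without mock replicate 1 and 2, and 804, 427 and 3426 without GA3 replicate 1, 2 and 3.

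After 60 min in ap1-15, GA20OX3 was at least 14.7-fold lower with GA3 (adjusted p = 5.36e-10), below background on the GA3 arrays. GA20OX2 changed by −3.46 ± 0.37 (adjusted p = 9.24e-05), GA3OX1 by −2.76 ± 0.17 (adjusted p = 5.76e-08) and GA20OX1 by −1.51 ± 0.19 (adjusted p = 0.000775). SCL3 (−1.17 ± 0.08), GID1B (−0.97 ± 0.08), XERICO (−0.72 ± 0.07), GID1A (−0.69 ± 0.11), IQD22 (−0.65 ± 0.10), SLY1 (−0.51 ± 0.08) and SAUR9 (−1.11 ± 0.17) fell. AT5G55150, which had risen at 30 min, changed by −4.66 ± 0.80 and AT5G14980 by −1.64 ± 0.31. ORA47, an AP2/ERF gene of jasmonate signalling, and AT1G23660 were at least 2.88-fold and 1.53-fold lower. Among rises, the cytochrome P450 genes CYP71A12 and CYP82C2 went up by 2.85 ± 0.52 and at least 4.74-fold, and the cytokinin oxidase gene CKX2 at least 1.31-fold. AT3G60270 (1.93 ± 0.31), AT1G36622 (1.29 ± 0.27), AT1G52800 (0.76 ± 0.16), AT5G62420 (0.74 ± 0.13), RTFL5 (0.70 ± 0.12), TCP9 (0.63 ± 0.10) and ZFP8 (0.57 ± 0.11) rose too. Of the 12 DELLA early targets 7 fell and 0 rose (9 lower when adjusted over the list alone; camera adjusted p = 8.08e-29, and 3.97e-08 with an estimated correlation). Of 10 GA synthesis genes 4 fell and 0 rose (4 when adjusted over the list alone; camera adjusted p = 6.15e-11, and 0.0014 with an estimated correlation). Floral identity genes were shifted up with 0 of 14 called (3 when adjusted over the list alone; camera adjusted p = 0.0297, and adjusted p = 0.514 with an estimated correlation). In all 19 genes rose and 109 fell, or 7 and 63 with slide as a random block and 2 and 9 with only the compared groups in the fit. Within slides 1 rose and 17 fell, 8 of them also called over all arrays, including GA20OX3, GA3OX1 (−2.70), SCL3, GID1B and XERICO but not GA20OX2 (−3.37, adjusted p = 0.073) or any other gene named above. The count became 50, 67 and 381 without mock replicate 1, 2 and 3, and 73 without GA3 replicate 3.

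Many calls were shared between the genotypes, which have no array in common. At 60 min 42 genes fell in both genotypes, against 0.242 if the calls were independent, and 3 rose in both, against 0.00666. At 30 min 38 fell in both, against 6.58, and 2 rose in both, against 5.55. Over all genes, which are not independent replicates, the changes of the genotypes correlated at 0.46 at 60 min (0.18 within slides) and at −0.30 at 30 min (0.15 within slides). The genes lower with GA3 in both genotypes at both times numbered 16, and 0 were higher in all 4 comparisons by limma. They were GA20OX3, GA3OX1, GID1B, SCL3, XERICO, NAP, NAC047, MYB78, the B-box factor gene BZS1, SAUR36, EPS1, AT1G62370, AT2G28690, AT2G34610, AT3G24420 and AT4G19700. NAP changed by −1.13 and −1.53 in wild type and by −1.29 and −0.77 in ap1-15 at 30 and 60 min, and MYB78 by −0.73, −0.98, −0.88 and −0.90. SCL3 and GID1B were also called within slides in all 4 comparisons, as 2 of the 16.

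**Figure D2:**
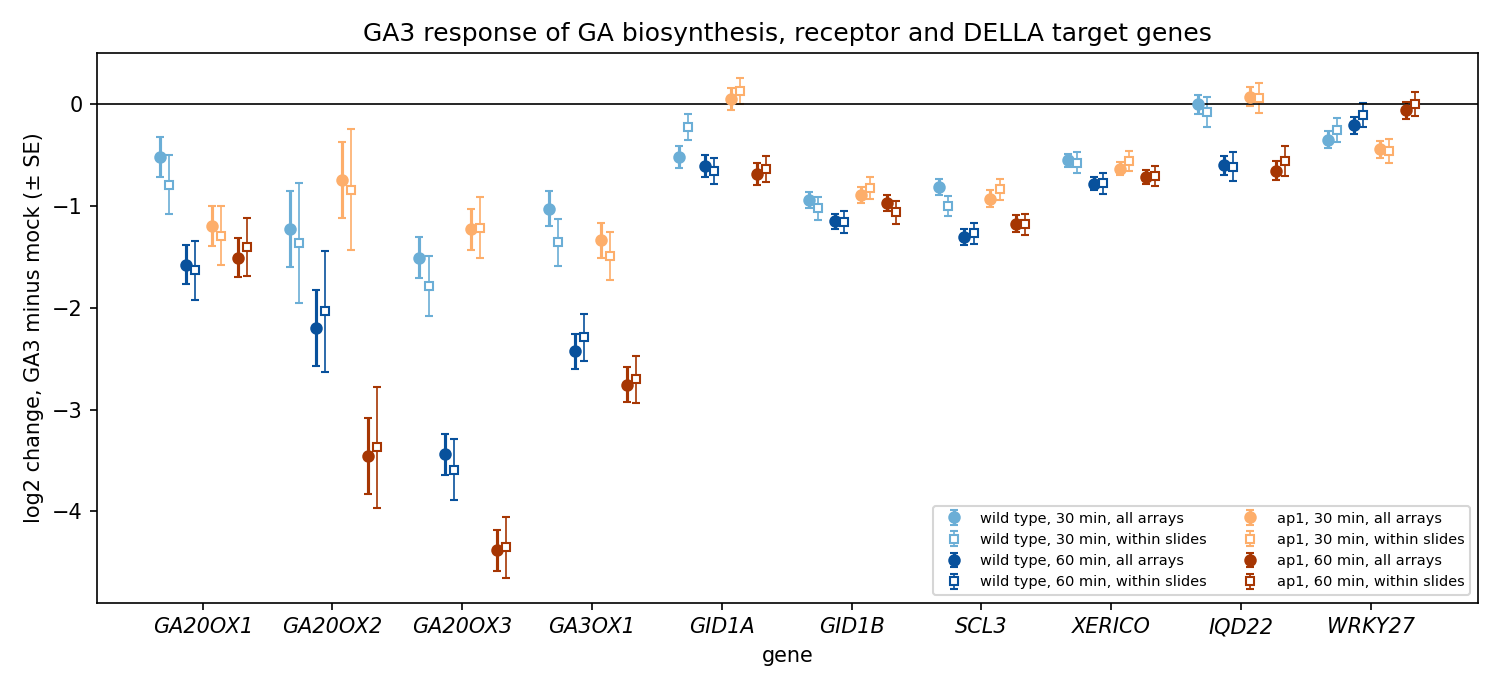
Change with GA3 in 10 genes of GA synthesis, perception and DELLA targets (vertical axis, log2 GA3 minus mock), by genotype and time; filled points use all arrays, open points the values within slides, and bars are standard errors from limma. GA20OX3 was not above background on the GA3 arrays at 60 min, where wild type was at least 4.49-fold and ap1-15 at least 14.7-fold lower with GA3.

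Averaging the genotypes gives their mean GA3 response, in which a gene can be called though it changed in 1 genotype alone. At 30 min GA20OX3 (−1.37 ± 0.14), GA3OX1 (−1.18 ± 0.12, adjusted p = 3.1e-05), RVE1 (−1.03 ± 0.12), GID1B (−0.92 ± 0.06, adjusted p = 5.66e-08), SCL3 (−0.87 ± 0.06), GA20OX1 (−0.86 ± 0.14) and XERICO (−0.59 ± 0.05) fell. JAZ2 and JAZ3 rose by 0.34 ± 0.07 and 0.26 ± 0.06. Within slides these genes were called too, GA3OX1 at −1.42 and GID1B at −0.92. At 60 min the GA synthesis genes GA20OX2 (−2.83 ± 0.26), GA3OX1 (−2.59 ± 0.12, adjusted p = 2.91e-10) and GA20OX1 (−1.54 ± 0.14) fell. So did SCL3 (−1.24 ± 0.06), GID1B (−1.06 ± 0.06), XERICO (−0.75 ± 0.05), GID1A (−0.65 ± 0.08), IQD22 (−0.63 ± 0.07), SLY1 (−0.48 ± 0.06), SAUR9 (−0.95 ± 0.12) and the flowering repressor gene TEM1 (−0.67 ± 0.13). In the other direction at 60 min, the DELLA genes GAI (0.38 ± 0.07), RGA (0.26 ± 0.04), RGL1 (0.38 ± 0.05) and RGL2 (0.44 ± 0.10) rose with the GA-inactivating oxidase gene GA2OX2 (0.51 ± 0.12). Among floral identity genes SEP2 (adjusted p = 0.0475, not above background in ap1-15 mock), MYB17 (0.34) and AP2 (0.22) rose at 60 min, 3 of 14 (3 when adjusted over the list alone; camera adjusted p = 0.00101, and adjusted p = 0.254 with an estimated correlation). The DELLA early targets had 5 of 12 members lower at 30 min and 8 at 60 min (8 and 11 when adjusted over the list alone; camera adjusted p = 5.54e-15 and 3.19e-31). GA synthesis had 3 of 10 members lower at 30 min and 4 at 60 min (5 lower and 1 higher, and 5 lower, when adjusted over the list alone; camera adjusted p = 2.52e-05 and 5.86e-11). These 4 calls hold with an estimated correlation, at an adjusted p of at most 0.0367. At 30 min 77 genes rose and 204 fell (147 and 199 within slides), or 175 and 167 with the other background correction and 28 and 90 with only the compared groups. At 60 min 123 rose and 401 fell (5 and 52 within slides, 55 and 249 with slide as a random block). Within slides SAUR9, TEM1, the DELLA genes, GA2OX2, SEP2, MYB17 and AP2 lost their call at 60 min, and the others named kept it. The count at 30 min became 182 without wild-type mock replicate 2, 164 without wild-type GA3 replicate 1 and 181 without ap1-15 mock replicate 2. The count at 60 min became 322 and 342 without wild-type mock replicate 1 and 2, and 290 and 905 without ap1-15 mock replicate 1 and 3.

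Whether ap1-15 responded otherwise than wild type was tested as the interaction of genotype and GA3. At 30 min the bHLH gene PAR2 (−0.71 ± 0.13, adjusted p = 0.00348), the brassinosteroid gene DWF4 (−0.55 ± 0.09, adjusted p = 0.00255) and the auxin response genes IAA1 (−0.65), IAA5 (−0.85) and IAA6 (−1.04) had a lower GA3 response in ap1-15. EXPA5 (0.84 ± 0.16, adjusted p = 0.00385), GAI (0.59 ± 0.14), GID1A (0.57 ± 0.15, adjusted p = 0.0196), GNL (0.75), the clock gene RVE8 (0.85) and the cold-response factor gene CBF2 (1.05) had a higher one. Higher and lower refer here to the signed change with GA3, not to its size. GID1A and GNL fell in wild type at 30 min, so their positive values mean a weaker fall or none in ap1-15. The GA synthesis list had 1 of 10 members called, KAO1 (−0.33), and the DELLA early targets 1 of 12, GID1A (1 and 1 when adjusted over the list alone; camera adjusted p = 0.382 and 0.929). At 30 min 78.6% to 80% of spots lay well above background in wild type with GA3 and 75.6% to 78.8% in mock. In ap1-15 it was 68.1% to 72.5% with GA3 and 73.5% to 76.6% in mock, a difference that runs with this interaction. In all 1804 genes had a higher and 2800 a lower GA3 response in ap1-15 at 30 min, but within slides 4 and 25, of which 11 were called both ways, AT3G24230 (3.15, and 3.89 within slides) among them but none of the genes named in this paragraph so far. AT3G24230 was not above background in mock, so its values are fitted and uncertain. With slide as a random block they numbered 397 and 908, and with only the compared groups 19 and 57. The reference genes GAPC1 (0.68) and UBC21 (0.34) were higher and ACT2 (−0.34) was lower in the same test, 3 of 10 (5 when adjusted over the list alone). At 60 min limma called 0 genes, with 489 at an unadjusted p under 0.05, and 0 within slides, with 486 unadjusted. Averaged over both times, SDR3 had a higher response in ap1-15 (0.55 ± 0.08), and IREG1, an iron transporter gene, AT5G35930 and AT1G04295 a lower one (−0.74 ± 0.12, −0.40 ± 0.06 and −0.36 ± 0.06), each at adjusted p = 0.0471, and none of the 4 was called within slides. With the other background correction 4 genes had a higher and 0 a lower response, SDR3 alone of the 4 keeping its call. Limma called 0 genes without a filter, with the mean of the probes, with an intensity trend, with a replicate block and with slide as a random block. With quantile normalization it called 76, of which 16 had a higher and 60 a lower response. For the 281 genes called on the mean of the genotypes at 30 min, the mean GA3 response was 0.383 in wild type and 0.740 in ap1-15. The difference was 0.357 (0.387 within slides). In a 2-sided exact permutation test over 400 relabelings p was 0.07, the smallest possible being 0.005. The mean signed level of these genes on the GA3 arrays lay between 0.913 and 0.971 in wild type and between 1.29 and 1.35 in ap1-15. With these ranges apart, p rested on the order of the small mock differences, so it does not show equal responses. The genes and their signs were chosen on these same arrays. Log2 differences between replicates with GA3 had standard deviations of 0.402 to 0.438 in ap1-15 and 0.207 to 0.270 in wild type. The choice may thus favour genes with a larger fitted change in ap1-15, so the separate ranges do not show a larger response either. For the 524 genes at 60 min the mean GA3 response was 0.482 and 0.570, a difference of 0.0882 (0.0278 within slides; exact permutation p = 0.355), but 0.296 (exact permutation p = 0.05) over the genes called with slide as a fixed term. With 1 array left out the difference at 60 min ran from 0.0117 (wild-type GA3 replicate 1) to 0.416 (ap1-15 mock replicate 3). Neither difference passed the test in the main fit. The difference at 30 min did pass with slide as a fixed term over the genes called in that fit (0.477, exact permutation p = 0.045), with the other background correction (0.264, exact permutation p = 0.04) and without any 1 of 5 ap1-15 arrays, so this call depends on the fit. The count at 30 min became 1984, 2006 and 8045 without wild-type mock replicate 1, 2 and 3, 3019 without wild-type GA3 replicate 3. It became 2279 without ap1-15 mock replicate 1 and 2641 without ap1-15 GA3 replicate 2. At 60 min it became 2 without ap1-15 GA3 replicate 1. The count averaged over both times became 4282 and 227 without mock replicate 3 at 30 min of wild type and ap1-15, 14 without wild-type GA3 replicate 3 at 60 min, 22 and 1119 without ap1-15 GA3 replicate 1 and 3 at 30 min, and 0 without any other array.

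The difference between ap1-15 and wild type without added GA was measured in the mock samples. In mock at 30 min AT3G03290 was 5.01 ± 0.30 higher in ap1-15 (adjusted p = 6.02e-08) and AT1G60180 at least 14.6-fold higher. The heat shock gene CLPB2 (2.39 ± 0.67), BAP2, a suppressor of cell death (2.26 ± 0.45), the calmodulin-like gene CML39 (AT1G76640, 2.01 ± 0.41), AT3G07250 (2.46 ± 0.44) and AT5G22520 (2.12 ± 0.32) were higher too. HULK3 (AT3G63070), a relative of the floral regulator gene HUA2, was lower (adjusted p = 0.00475), above background on 1 of 3 ap1-15 arrays in each condition, the plant defensin gene PDF1.2 changed by −2.93 ± 0.76 (adjusted p = 0.0171), and AT4G07965 was at least 2.78-fold lower. Among floral identity genes SEP1 (−1.29) was lower, AP3 at least 2.88-fold and SEP2 at least 2.11-fold lower, and FUL higher (0.53), so that with AP1 4 of 14 were lower and 1 higher (10 and 1 when adjusted over the list alone; camera adjusted p = 0.00242, and adjusted p = 0.526 with an estimated correlation). At 60 min 3 of 14 were lower and 1 higher (3 and 2 when adjusted over the list alone; camera adjusted p = 0.189). The lower ones were AP1, LMI1 (−0.75) and SEP2 (at least 1.16-fold) and the higher one FUL (0.74), whereas SEP1 was at −0.33 (adjusted p = 0.543) and AP3 was not called (adjusted p = 0.243). At 30 min GNL (−1.07) and GNC (−0.73) were lower with GUN4 and CRD1, 4 of 14 GATA factor and chlorophyll genes (4 when adjusted over the list alone; camera adjusted p = 0.00242, and adjusted p = 0.526 with an estimated correlation). None of these 4 was called at 60 min, where PORB (−0.59) and PORC (−0.19) were lower (3 when adjusted over the list alone; camera adjusted p = 0.263). Early auxin response genes had 6 of 21 members higher at 30 min and 7 at 60 min (13 higher and 1 lower, and 13 higher, when adjusted over the list alone; camera adjusted p = 8.89e-05 and 1.81e-09, but 0.526 and 0.293 as adjusted p with an estimated correlation). In mock at 60 min AT3G03290 was 5.30 ± 0.30 higher, AT1G60180 at least 9.32-fold and AT5G55150 at least 8.78-fold higher. The nitrate transporter gene NRT2.6 (2.77 ± 0.60), the heat shock gene HSP17.6A (2.76 ± 0.85), DREB19 (2.17 ± 0.40) and the plastid sugar phosphate transporter gene GPT2 were also higher. HULK3 (adjusted p = 0.0063), CYP76G1 (−2.21 ± 0.35), AT3G02100 (−2.50 ± 0.44), AT1G15540 (−2.35 ± 0.28) and AT1G52790 (−2.19 ± 0.29) were lower. At 30 min 1803 genes were higher and 1774 lower, and at 60 min 1332 and 1743. With quantile normalization they numbered 1746 and 1947, and 1443 and 1376, so the more frequent direction turned at both times, whereas with the other background correction they numbered 2052 and 1508, and 1206 and 2228. With slide as a random block they numbered 966 and 757, and 714 and 767, and at 30 min 469 and 219 with only the compared groups. The genotypes never shared a slide. The counts became 1718, 1990 and 6322 without wild-type mock replicate 1, 2 and 3 at 30 min, 2056 and 1760 without ap1-15 mock replicate 1 and 2. They became 1299 and 1533 without wild-type mock replicate 1 and 2 at 60 min, and 1970 and 1762 without ap1-15 mock replicate 1 and 3.

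Over the mean of the 4 conditions, many floral identity genes were lower in ap1-15, and many early auxin, touch and jasmonate genes were higher. SEP1 changed by −0.94, SEP3 by −0.46, SEP4 by −0.30 and LMI1 by −0.58, whereas FUL, a close relative of AP1, was 0.47 higher and AP2 0.09. UFO and AG, above background on 5 of 12 wild-type and 0 of 12 ap1-15 arrays, SEP2 (9 and 1 of 12) and AP3 (10 and 4 of 12) were lower as well. With AP1, 9 of 14 floral identity genes were lower and 2 higher (camera adjusted p = 0.0326, and adjusted p = 0.499 with an estimated correlation). Early auxin response genes had 16 of 21 members higher and 0 lower, such as GH3.3 (0.79), SAUR15 (0.66) and IAA2 (0.43) (camera adjusted p = 4.18e-07, and adjusted p = 0.378 with an estimated correlation). Touch and rapid stress genes had 12 of 17 higher and 2 lower, with ZAT12 (1.21), WRKY40 (1.14) and XTH22 (1.02) among the higher and CBF3 (−0.67) among the lower (camera adjusted p = 1.29e-05, and adjusted p = 0.378 with an estimated correlation). Jasmonate genes had 7 of 17 higher and 0 lower, all of the JAZ family (JAZ8 and JAZ10 both 0.70; camera adjusted p = 0.00786, and adjusted p = 0.559 with an estimated correlation). Expansins and XTHs, which act on cell walls, had 10 of 22 higher and 3 lower (camera adjusted p = 0.0131, and adjusted p = 0.378 with an estimated correlation). Root markers had 6 of 11 higher and 1 lower (camera adjusted p = 0.014, and adjusted p = 0.378 with an estimated correlation). GATA factor and chlorophyll genes had 8 of 14 lower, such as GNC (−0.50) and PORB (−0.35), and mitotic genes 7 of 15 lower, with 0 higher in both (camera adjusted p = 0.0326 and 0.029, but 0.559 as adjusted p with an estimated correlation for both). The other lists were not called. GA synthesis had 2 of 10 higher (GA20OX3, not above background with GA3 at 60 min in either genotype, and GA20OX2 by 0.48) and 5 lower (camera adjusted p = 0.39), GA deactivation 3 of 8 higher and 1 lower (0.529), and GA perception 3 of 12 and 1 (0.312). DELLA early targets had 3 of 12 higher and 2 lower (camera adjusted p = 0.482) and the GASA family 1 of 7 and 1 (0.647). Brassinosteroid genes had 3 of 11 higher and 2 lower (camera adjusted p = 0.619), growth bHLH genes 5 of 17 and 5 (0.54), and flowering time genes 3 of 18 and 6 (0.686). Anther markers had 0 of 3 higher and 2 lower (camera adjusted p = 0.529), shoot meristem markers 0 of 7 and 4 (0.482), clock genes 4 of 15 and 2 (0.201) and reference genes 5 of 10 and 0 (0.0639). When adjusted over the list alone the counts were the same, except 2 higher and 7 lower for GA synthesis, 5 and 2 for GA deactivation, 4 and 3 for DELLA early targets, 3 and 7 for flowering time, and 3 and 2 for the clock.

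Beyond the lists, AT3G03290 was higher in ap1-15 over the 4 conditions (adjusted p = 8.56e-14), above background on 12 of 12 ap1-15 and 6 of 12 wild-type arrays. HSP17.6A, not above background in mock at 30 min, AT5G22520 (2.00 ± 0.16), GPT2 (1.88 ± 0.18), CYP81F2, of indole glucosinolate synthesis (1.74 ± 0.20), and the histone deacetylase gene HDA18 (1.68 ± 0.10, adjusted p = 1.69e-09) were higher. HULK3 (adjusted p = 5.78e-07, above background on 4 of 12 ap1-15 arrays), AT3G05070 (−1.92 ± 0.12), MEE51 (−1.83 ± 0.06, adjusted p = 4.85e-13), AT3G02100 (−1.78 ± 0.22) and AT1G15540 (−1.64 ± 0.14) were lower, and so was FOP1, a gene of petal opening, not above background on any ap1-15 array. In all 4568 genes were higher and 7550 lower, of which 125 and 209 by at least 2-fold.

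How the GA3 response moved from 30 to 60 min was tested over both genotypes as an interaction. GA3OX1 (−1.41 ± 0.17, adjusted p = 0.00154), GA20OX2 (−1.84 ± 0.37, adjusted p = 0.0376), IQD22 (−0.66 ± 0.10, adjusted p = 0.00753) and GA20OX3 (adjusted p = 5.35e-06, with GA3 arrays not above background at 60 min) had a response further down at 60 min. RVE1 (0.87 ± 0.17, adjusted p = 0.0358) had one less far down. GA synthesis had 3 of 10 members lower and DELLA early targets 3 of 12, with 0 higher in both (4 lower, and 5 lower and 1 higher, when adjusted over the list alone; camera adjusted p = 2.54e-06 and 2.33e-09, and 0.0208 and 8.66e-05 with an estimated correlation). In all 33 genes were higher and 67 lower (32 and 138 with the other background correction), and within slides 10 and 8, of which 6, GA20OX3 but none of the other genes named above, were called both ways. With slide as a random block 11 were higher and 21 lower. At 30 min in wild type the count became 64 and 54 without mock replicate 1 and 2 and 44 and 52 without GA3 replicate 1 and 3, and at 60 min 47, 45 and 58 without mock replicate 1, 2 and 3 and 49 without GA3 replicate 2 or 3. At 30 min in ap1-15 it became 58 and 53 without mock replicate 1 and 2, and at 60 min 49, 50 and 342 without mock replicate 1, 2 and 3 and 53 without GA3 replicate 2.

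Mock samples at 60 min against mock at 30 min show what changed after spraying without GA3. Of 17 touch-responsive and rapid stress genes 13 fell and 2, CBF1 and CBF3 of the cold response, rose (13 and 2 when adjusted over the list alone; camera adjusted p = 1.81e-10, and adjusted p = 0.213 with an estimated correlation). XTH22, also known as TCH4, changed by −2.91 ± 0.16 (adjusted p = 6.76e-10), the zinc finger gene SZF1 by −2.56 ± 0.13 (adjusted p = 1.71e-10), ERF105 by −2.46, TCH2 by −1.56 and WRKY40 by −1.42. The largest falls also held PHI-1 (−3.32 ± 0.13, adjusted p = 1.24e-11), the phloem protein genes PP2-B13 (−2.75 ± 0.27) and PP2-B14, not above background in wild type at 60 min, SAUR48 (AT3G09870, −2.65 ± 0.21), WRKY18 (−2.60 ± 0.12), the mitochondrial carrier gene DIC2 (−2.46 ± 0.14), AT2G32200 (−2.78 ± 0.17) and AT4G29780 (−2.49 ± 0.15). Among rises, CYP707A2, which encodes an abscisic acid 8′-hydroxylase, went up by 2.31 ± 0.20 (adjusted p = 9.33e-08), and PKS4, a phytochrome kinase substrate gene, by 3.15 ± 0.45. AT1G07400 (2.69 ± 0.42) and AT5G50335 (2.63 ± 0.18) rose too. The phosphatase gene HAI2, the heat shock genes HSP17.6A and HSP17.6II, AT1G71000 and AT1G43195 rose from signals not above background at 30 min in 1 or both genotypes, so no size is given. Growth bHLH genes had 10 of 17 members higher and 0 lower, such as BEE3 (1.07) and PIF3 (1.08) (11 and 1 when adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.294 with an estimated correlation). Expansins and XTHs had 11 of 22 lower, 10 of them XTHs, and 5 higher, all expansins such as EXPA1 (1.26) (11 and 5 when adjusted over the list alone; camera adjusted p = 0.0115, and adjusted p = 0.294 with an estimated correlation). Jasmonate genes had 6 of 17 lower and mitotic genes 7 of 15, with 0 higher in both (7 and 9 when adjusted over the list alone; camera adjusted p = 0.0179 and 0.00118, but 0.702 and 0.554 as adjusted p with an estimated correlation). In all 5448 genes rose and 3853 fell, 275 and 360 of them by at least 2-fold, and no slide held mock samples of both times.

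**Figure D3:**
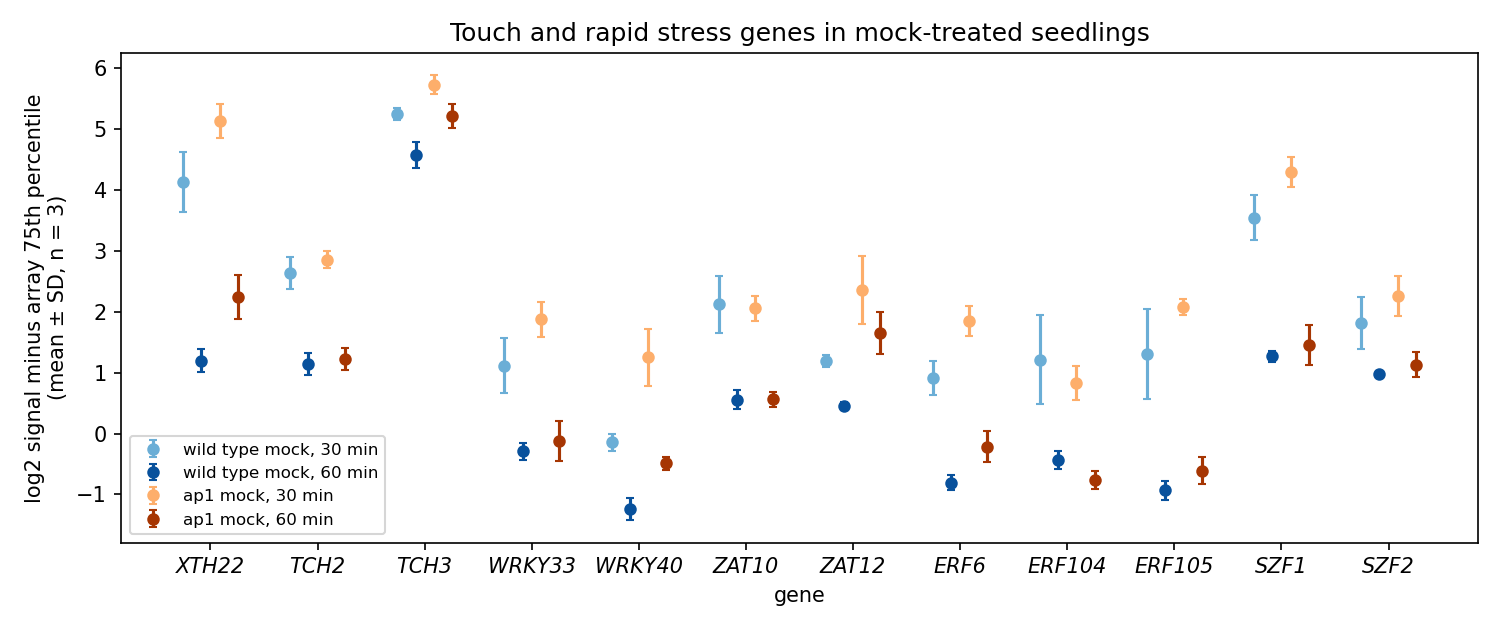
Mean signal of 12 touch-responsive and rapid stress genes in mock samples (vertical axis, log2 relative to the 75th percentile of the array), by genotype and time; bars are standard deviations of 3 arrays. XTH22 and SZF1 lie lower at 60 min than at 30 min, by −2.91 and −2.56 over both genotypes.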

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

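Of the tests in this part, those of the slide layout and of sequence differences under probes were chosen only after the result was seen.

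The first pattern is the interaction of genotype and GA3 at 30 min, where 4604 genes responded otherwise in ap1-15 than in wild type by limma's test of the difference. Against signal intensity as its cause, the share of called genes that were higher was 34.9% among the dimmest and 31.6% among the brightest, 3.26 points apart. This does not address a difference in background between groups. With GA3 78.6% to 80% of spots lay well above background in wild type and 68.1% to 72.5% in ap1-15. In mock it was 75.6% to 78.8% and 73.5% to 76.6%, and the part of this difference was not tested. The slide layout stays open. The median signed interaction was 0.50 over all arrays and 0.23 within slides (quartiles 0.15 and 0.40). This ratio of 0.465 met the bound of under 0.5 set for slides as the cause. The condition on signs was not met, since 99.1% of the genes kept theirs. That condition could hardly be met, because both values use the GA3 arrays and mock replicate 3 and the genes were chosen over all arrays. For GA3 in wild type at 30 min 100% kept their sign, although 5 of 409 genes were also called within slides. The within-slide value rests on 1 mock array per genotype, and mock replicate 3 lay farther from replicates 1 and 2 (standard deviation 0.443 in wild type and 0.408 in ap1-15) than these from each other (0.257 and 0.265). Single arrays also stay open, since 1974 of the genes, a share of 0.429, remained called without wild-type mock replicate 1. Slides, single arrays, signal intensity, background and a genotype difference in the GA3 response therefore cannot be told apart, and each may contribute.

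The second pattern is the difference between ap1-15 and wild type over the mean of 4 conditions, 12118 genes. A chromosome segment around AP1 carried along with the mutation is argued against as the cause of the large changes, because 1 of the 200 nearest tested loci changed at least 2-fold against 2.48 expected from 278 of 22462 loci, a ratio of 0.404. Segments elsewhere in the genome were not tested, and shares per chromosome cannot show a short one. The genes with another probe and locus numbers from AT5G57565 to AT5G61270 were all higher in ap1-15 with both probes. Among them were AT5G57565 (1.09), AT5G58680 (1.42), AT5G59490 (1.35) and PIF7 (AT5G61270, 1.01). A segment of chromosome 5 that differs between the lines therefore stays open. The share of loci changed at least 2-fold ran from 0.912% on chromosome 1 to 1.60% on chromosome 5. Differences between slides stay open, since genotype and slide are confounded: the genotype differences in mock at 30 and at 60 min, on separate slides, correlated at 0.459 across genes (Spearman 0.438), between the bounds set, with 690 genes higher and 540 lower at both times against 93.6 and 121 expected. Sequence differences under probes stay open because 31 of the 334 genes with at least 2-fold change, or 9.28%, had another probe, whose median change was 1.09 times that of the first. The loss of AP1 and any other difference between the lines remain open as biological explanations, and none was tested.

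The third pattern is the change from 30 to 60 min in mock, 9301 genes. Independent differences between slides are argued against as its cause, since the changes in wild type and in ap1-15, on separate slides, correlated at 0.597 across genes (Spearman 0.534). Signal intensity stays open, as 48.6% of the dimmest and 70.4% of the brightest called genes were higher, 21.7 points apart and between the bounds set. A technical difference common to all samples of a time was not tested, and the time since spraying may be a biological cause that the design cannot separate from it.

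Relabelings of the arrays were counted for each number of genes called, on the genes measured on all arrays. With 10 splits a share under 0.05 is out of reach, and 1 split, the real one, called the most genes: 401 for wild type at 30 min (highest other 140), 65 at 60 min (0), 1631 for ap1-15 at 30 min (60), 123 at 60 min (10), 3568 for the genotypes in mock at 30 min (2331) and 3072 at 60 min (0). Of 100 splits, 1, the real one, reached the real count for GA3 in both genotypes at 60 min (520, highest other 4) and for ap1-15 against wild type over 4 conditions (12092, highest other 6843). The same held for time and GA3 (100, highest other 54) and for mock over time (9290, highest other 5812). These shares lay under the 0.05 set beforehand. The share was also under 0.05 for the interaction at 30 min, where 2 of 100 splits called as many (4605, highest other 5244, with wild-type mock replicate 3 and GA3 replicate 2 exchanged). For its mean over both times 3 of 100 did (4, highest other 23). Mixing arrays adds real differences to the spread within groups, which favours the real grouping, so a small share does not exclude chance. The splits exchanged arrays without regard to slides, which the real groups follow, so they do not exclude slides as a source of the calls, and within slides the interaction at 30 min called 29 genes. The share did not lie under 0.05 for GA3 in both genotypes at 30 min, where 5 of 100 splits called as many as the real 277, up to 4358, many times the real count. Exchanging GA3 and mock in 1 genotype turns that comparison into the interaction, whose source at 30 min stays open. Whether this gave the higher counts was not tested. For the interaction at 60 min all 100 splits reached the real 0 of limma, with 489 genes at an unadjusted p under 0.05, and the highest other was 520.

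Further results stood out because effects differed between genotypes or times in a direct test. The genes named for their fitted interaction at 30 min toward a higher response in ap1-15 were AT2G24255 (4.04), bZIP75 (3.85), AT2G02110 (3.73), a transcript without a locus (3.72), AT5G44770 (3.70), AP3 (3.64), AT3G24230 (3.15), AT1G30180 (3.06), 4CL8 (2.95) and AT2G07719 (2.60). All but 4CL8 and AT2G07719 were not above background in at least 1 of the compared groups, so the sizes and order of these fitted values are not determined. Those named for a lower response were transcripts without a locus, with fitted values of −4.36, −4.28, −3.98, −3.65 in 3 of them, −3.56, −3.52, −3.28 and −3.25, of which 6 were not above background in ap1-15 with GA3 and have the same limit. Averaged over both times 4 genes were called: SDR3 (0.55), IREG1 (−0.74), AT5G35930 (−0.40) and AT1G04295 (−0.36). The interaction of time and GA3 called 100 genes. Touch genes and mitotic genes were called for the interaction of genotype and GA3 at 60 min (camera adjusted p = 0.000359 and 0.0299, but 0.881 as adjusted p with an estimated correlation for both), and touch genes for its mean over both times (camera adjusted p = 0.0271, and adjusted p = 0.967 with an estimated correlation). For time and GA3 the called lists were GA synthesis (camera adjusted p = 2.54e-06), DELLA early targets (2.33e-09), early auxin response (0.0163), jasmonate (0.000216), touch (0.0163), floral identity (0.00634) and mitotic genes (7.05e-07), and all but the first 2 lost the call with an estimated correlation, at an adjusted p of 0.363 to 0.509.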

How the results depend on the processing

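The normexp correction on median signals, the fixed slide term, the fit without 2 arrays that stood apart (wild-type GA3 replicate 3 at 60 min and ap1-15 GA3 replicate 2 at 30 min) and the list loci of the reference table were chosen after seeing the data. Normexp on mean signals (the column is absent), a scan-date block (1 date) and other AP1 probes (there is 1) were not run, and the series table equals the scanner signal and so tests nothing. Signal over background limits dim genes, since 68.1% to 80% of spots lay well above it. GA20OX3, GA3OX1, SCL3, GID1B and XERICO at 60 min in wild type, and GA20OX3, GA3OX1 and SCL3 in ap1-15, kept their call in every alternative that tested them and with each array left out. The filter for probes above background on all arrays left GA20OX3 untested. AP1 stayed lower wherever it was tested, from −3.10 to −2.92 with 1 array left out and −1.47 with normexp, and was not tested with that filter or with slide as a fixed term. Every scaling moved the median of all genes by under 0.1 log2. Replicate numbers showed no pairing: deviations correlated at −0.00569 on average for the same number and 0.00278 for different numbers, and with a replicate block 604 of 650 gene calls and 62 of 62 list calls were the same, with 233 genes for wild-type GA3 at 30 min and 0 for the mean interaction of genotype and GA3.

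Other results that left their range are given by setting, and unless the setting tests fewer genes or arrays the cause was not tested. Quantile normalization gave 76 for the mean interaction. Without a filter GA3 in wild type at 30 min gave 82, in ap1-15 at 60 min 80, the mean interaction 0 and time by GA3 50; with probes above background on all arrays wild type at 30 min gave 655 and time by GA3 61. The mean of probes gave 0 for the mean interaction, and turned PIF1 for both genotypes at 60 min (0.0823), BRI1 in the interaction at 30 min (−0.49) and over 4 conditions (−0.0695) and GA2OX2 over 4 conditions (−0.21). An intensity trend gave 709 for wild type at 30 min and 0 for the mean interaction. Slide as a random block gave 47 and 42 for GA3 in wild type at 30 and 60 min, 848 and 70 in ap1-15, 304 for both genotypes at 60 min, 1305 for the interaction at 30 min, 0 for its mean, 1723 and 1481 for the genotypes in mock, and 32 for time by GA3. Slide as a fixed term gave 14, 5, 376 and 18 for the same GA3 comparisons, 57 for both genotypes at 60 min, 29 for the interaction at 30 min, 18 for time by GA3 and −0.0575 for BRI1 in the interaction, and the difference in response size at 30 min was 0.477 (exact permutation p = 0.045). Normexp gave 170 for time by GA3 and 0.264 for that size (exact permutation p = 0.04). Without the 2 arrays wild type at 60 min gave 33, ap1-15 at 30 min 356, both genotypes at 60 min 330, the interaction at 30 min 2220, its mean 0 and time by GA3 58. With only the compared groups in the fit, wild type at 30 min gave 0 in limma, ap1-15 32 and 11, both genotypes at 30 min 118, the interaction at 30 min 76 and the genotypes in mock at 30 min 688. An estimated correlation kept 13 of 62 list calls and fry kept 36. The size difference at 60 min was 0.296 with slide as a fixed term (exact permutation p = 0.05).

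With each array left out in turn the ranges were 23 to 5720 and 24 to 58 for GA3 in wild type, 427 to 3426 and 50 to 381 in ap1-15, and 164 to 387 and 290 to 905 in both, at 30 and 60 min. They were 1984 to 8045, 0 to 2 and 0 to 4282 for the interaction at 30 min, at 60 min and its mean, and 1718 to 6322, 1299 to 2661 and 11296 to 12349 for the genotypes in mock at 30 and 60 min and over 4 conditions. Time by GA3 gave 44 to 342, mock over time 7688 to 10980, called named genes 548 to 634, called lists 54 to 67, and the size difference 0.183 to 0.550 at 30 min and 0.0117 to 0.416 at 60 min. At 30 min the size difference passed 0.05 without ap1-15 mock replicate 1 (0.286) or 3 (0.459) or ap1-15 GA3 replicate 1 (0.453), 2 (0.368) or 3 (0.550). The report names each array that moved a count.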

Other observations

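Genes of GA synthesis and signalling also changed between the mock samples of 30 and 60 min. The inactivating oxidase gene GA2OX2 was lower at 60 min (−1.37) and the synthesis gene GA3OX2 higher (1.09). Among the DELLA early targets IQD22 (0.99), XERICO (0.76), SCL3 (0.63) and GID1B (0.30) were higher at 60 min, and BHLH137 (−1.03) was lower. Of the 12 targets 4 rose and 2 fell (4 and 2 when adjusted over the list alone; camera adjusted p = 0.154), of 10 GA synthesis genes 3 rose and 0 fell (3 when adjusted over the list alone; camera adjusted p = 0.409), and of 12 genes of GA perception 3 rose and 3 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.878). Clock genes had 7 of 15 members higher and 1 lower (8 and 1 when adjusted over the list alone; camera adjusted p = 0.13), with RVE1 (0.80), PRR9 (0.61) and GI (0.53) higher and LUX (−0.25) lower. Time and slide cannot be separated for these values.

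Over the mean of 4 conditions, clock and flowering time genes differed between the genotypes in both directions. TOC1 (0.60), BOA (0.82), CCA1 (0.35) and LHY (0.26) were higher in ap1-15 and RVE1 (−0.29) was lower. By locus number TOC1 (AT5G61380) and BOA (AT5G59570) lie within or next to the range of higher genes on chromosome 5 given above. So do FUL (AT5G60910), ZAT12 (AT5G59820), XTH22 (AT5G57560) and EF1A (AT5G60390). Whether a segment there accounts for their values was not tested. Of the flowering genes SPL5 (0.39) was higher, and SPL9 (−0.37), SPL3 (−0.32), SVP (−0.27) and SOC1 (−0.21) were lower. The GA-inactivating oxidase gene GA2OX1, not above background in ap1-15 with GA3 at 30 min, was lower, and the root hair expansin genes EXPA18 (0.47) and EXPA7 (0.25) were higher. The reference genes GAPC1 (0.40), EF1A (0.20), UBC21 (0.14), UBC9 (0.11) and SAND (0.10) were higher in ap1-15 as well, 5 of 10, so small shifts of this size also appear in genes often used for scaling. Genotype and slide cannot be separated for these values.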
